A study of Galleria mellonella with 6 samples.

How the data were processed

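Antennae of the greater wax moth Galleria mellonella were collected from adults of each sex just after they left the pupa, about 300 per sex per the labels' protocols, and larvae had been reared on old comb at 34 °C and 65% relative humidity. Total RNA was extracted and sequenced on an Illumina HiSeq instrument, per the labels' protocols. There were 3 female and 3 male libraries. The labels do not say that the 3 libraries of a sex came from separate animals, so p-values measure the spread between these libraries, which may be technical.

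Each deposited file listed assembled transcripts (unigenes) of 1 library with their length, an estimated count of reads, an FPKM value (fragments scaled by transcript length and library size) and the descriptions of best database hits. The deposited read counts were expected counts, as the authors' values were not all whole, and between 79.3% and 81.3% of them were whole numbers in a library, taken as exactly whole (a tolerance of 0) at the 2 decimals the files give. The deposited FPKM values followed from those expected counts, the library total and a length shortened by 298 to 312 bases. The assembler, the counter and the annotation tools were not given in the sources used here. The lowest FPKM in any deposited file was 0.31, so unigenes at or below 0.3 FPKM were unlisted, and an unlisted unigene was below this limit and not necessarily at 0. Of 151118 unigenes listed in at least 1 file, 20615 were listed in all 6, and 73454 (48.6%) had a best protein hit in the NR database. None of the best-hit accessions was found in the RefSeq gene table of the species (0 matches), so names are those of the best hits, mostly from other insects, and no genome position is given. Unigenes that are copies of one gene can share or split reads, so the level of any single unigene is uncertain to that degree.

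Expected counts were rounded to whole numbers, an unlisted unigene entered as 0, and CPM values were the reads of a unigene scaled to a common library total. Differences were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM scaling, filterByExpr), male against female over all 6 libraries with no replicate block. Adjusted p is Benjamini-Hochberg over the 31688 unigenes tested, with a threshold of 0.05, and the standard error (SE) of a log2 fold change is its size divided by the square root of F. Log2 fold changes are male over female unless stated. Those of edgeR use TMM scaling, while CPM values, their ratios and list sums do not. The TMM factors were 1.039, 1.083 and 1.097 in female libraries and 0.936, 0.845 and 1.024 in male libraries. CPM ratios therefore lie somewhat further toward females than the log2 fold changes. Because the design has 3 libraries per sex, an exact two-sided permutation test of a single value cannot give a p below 0.1.

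A total of 33 gene lists were fixed, before the data were examined, as word patterns on the hit descriptions. They held 6 chemosensory families: odorant-binding proteins, chemosensory proteins, odorant receptors, gustatory receptors, ionotropic receptors and sensory neuron membrane proteins. Other lists held detoxifying and odorant-degrading enzymes (cytochrome P450s, carboxylesterases, glutathione S-transferases, UDP-glycosyltransferases, aldehyde oxidases with alcohol dehydrogenases), and fatty acyl desaturases and reductases. Lists for other tissues and cell types covered sensory cilium, neuronal, amine and neuropeptide receptor, glial, muscle, photoreceptor, hemocyte and immune, fat body, ovary and egg, and testis genes. The rest covered sex determination, cuticle, tanning and melanin, heat shock, cytosolic ribosome, mitochondrial respiratory chain, juvenile hormone and ecdysone, circadian clock, and transposon, viral and microbial transcripts. The ionotropic receptor list also holds glutamate receptors of the same superfamily. Word patterns took some unrelated members. Of the tanning list 11 of 82 and of the testis list 13 of 94 matched by an organism name, and of the cilium list 98 of 302 matched mainly by the adjective inactive. Of the 343 viral members 18 were UDP-glycosyltransferases. Lists with at least 5 tested members were compared with the other unigenes by camera (limma 3.58.1, preset correlation of 0.01), with an estimated correlation and fry as alternatives. Summed CPM per list was compared by the exact permutation test.

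Unigenes were named by a rule also fixed then. It took the 8 called unigenes per direction with the smallest adjusted p, a log2 fold change of at least 1 and no overlap of the sexes. It took the 2 most abundant members and any called members of each chemosensory family. It further took the most abundant co-receptor, each pheromone-binding protein, both general odorant-binding proteins, both sensory neuron membrane proteins, doublesex, fruitless and vitellogenin, and called members of other lists with at least 3 calls. The last part and the female direction of the first part selected none. Other names were chosen after their values were seen, and the text says so.

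Alternatives chosen before the data were examined were RLE size factors, DESeq2 1.42.0, no filter, a stricter filter, the replicate number as a block, each library left out, only unigenes listed in every file, glmTreat against a log2 fold change of 1, and counts summed per best protein hit. A pseudocount alternative was not run because the files hold counts. Alternatives chosen after seeing the data filled unlisted values at 0.15 FPKM, left out unigenes with best hits to other organisms, left out list members matched by an organism name or the adjective inactive, and combined settings. Tables were made with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

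The test was tried on simulated data drawn from the means of these libraries. Over the 31688 tested unigenes it recovered 0 of 67 unigenes changed 2-fold, 4 of 67 changed 4-fold (6%) and 23 of 66 changed 16-fold (34.8%), with 3 false calls. Over the 20118 unigenes listed in every file it recovered 5 of 67, 36 of 67 and 64 of 66, with 6 false calls. The common dispersion was 0.696 over all tested unigenes and 0.142 over those listed in every file. In the camera test, 2 of 100 unchanged simulated lists of 30 members had p under 0.05. These lists were random and each unigene was drawn independently, so their members were not correlated. The simulation therefore cannot show the error rate of camera for lists whose members move together.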

Results

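The series compared gene expression in the antennae, the main olfactory organs, of female and male greater wax moths, with chemosensory genes as its subject. The 3 female libraries held 16603283, 19269971 and 17523822 reads on listed unigenes. The 3 male libraries held 18413973, 17794687 and 18866170. Between 58572 and 85323 unigenes were listed per library, the most in female replicate 2. Pairwise correlations of log2 expression ranged from 0.72 to 0.824, and libraries did not group by sex on the first principal component, which took 30% of the variance. On it male replicate 3 lay at -37, among the female libraries (-177.1 to -30.7), while male replicates 1 and 2 lay at 93 and 200.1. Male replicate 3 also correlated more with the female libraries (0.797 to 0.818) than with male replicates 1 and 2 (0.793 and 0.765). Female replicate 2 held 34822 unigenes listed in no other library, carrying 6.97% of its reads, against 4829 to 7197 such unigenes in each of the other 5 libraries.

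The first comparison asked which unigenes differed between the sexes. A unigene whose best hit is the juvenile hormone binding protein precursor of this species (Cluster-99082.20726), a carrier of juvenile hormone in the hemolymph, was 116-fold higher in males. It stood at 9619 ± 1315 CPM in males against 82.6 ± 14.1 CPM in females (SD, n = 3 per sex). Its log2 fold change was 7.04 ± 0.26 (SE), with an edgeR adjusted p of 0.00136. A unigene matching ATP-binding cassette sub-family C member 4 (Cluster-99082.19217), a multidrug resistance type transporter, stood at 28.5 ± 3.49 FPKM in males (SD, n = 3) and was unlisted in all 3 female libraries. This puts it at least 95.1-fold above the listing limit of 0.3 FPKM (edgeR adjusted p = 0.0105). Summed over the 4 unigenes with the same protein hit, however, the transporter stood at 208 ± 24.6 CPM in males against 88.2 ± 7.51 CPM in females, a log2 fold change of 1.40 (edgeR adjusted p = 0.04 over summed hits).

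These were the 2 calls among 31688 unigenes, both higher in males, and 1555 unigenes had an unadjusted p under 0.05. The transporter lost its call without female replicate 2 (adjusted p = 0.0519) and without male replicates 1, 2 and 3 (adjusted p = 0.179, 0.126 and 0.0661), while the hormone binding protein kept its call in each of these fits. DESeq2 called 196 unigenes, of which 194 were unlisted in every library of 1 sex.

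Among the 20118 tested unigenes listed in every file, 4 were higher in males and 3 in females by edgeR. Of the 6 besides the hormone binding protein, all except olfactory receptor 15 were named after their values were seen. In females the UDP-glycosyltransferase UGT42A1 (Cluster-54295.1), of a family that conjugates small lipophilic compounds, stood at 86.3 ± 17.1 CPM against 14.3 ± 2.81 CPM in males (SD, n = 3 per sex; edgeR adjusted p = 0.00703). A cytochrome P450 matching CYP324A1 (Cluster-99082.35859) and a unigene matching olfactory receptor 15 (Cluster-99082.9723) were also higher in females, with an edgeR adjusted p of 0.0347 for each. Male libraries held more of 3-dehydroecdysone 3alpha-reductase (Cluster-99082.45341), an enzyme of ecdysteroid metabolism, at 136 ± 43.5 CPM against 15.2 ± 1.5 CPM (SD, n = 3 per sex; edgeR adjusted p = 0.00703). The other 2 male calls matched cytosolic 10-formyltetrahydrofolate dehydrogenase (Cluster-99082.31958) and a probable 3-hydroxyacyl-CoA dehydrogenase (Cluster-99082.37634), with edgeR adjusted p of 0.00784 and 0.0098. Over all tested unigenes the adjusted p of these 6 ranged from 0.0663 to 0.316, and without female replicate 2 the count among unigenes listed in every file was 2.

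**Figure D1:**
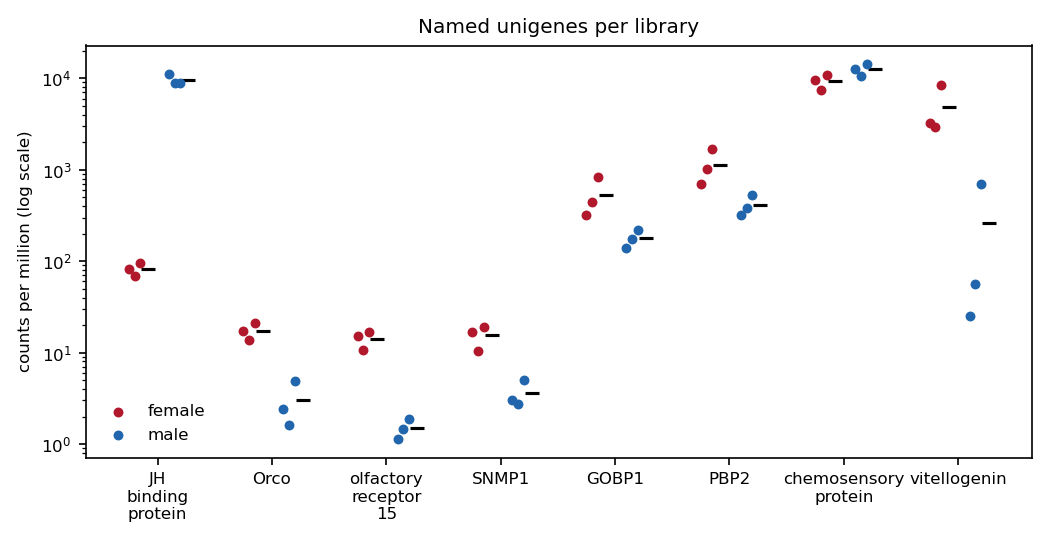
Expression in CPM (log scale) of 8 named unigenes in each of the 3 female and 3 male libraries, with points for libraries and a dash for the mean of each sex. The juvenile hormone binding protein is the unigene in this plot that passed the threshold over all tested unigenes, with means of 82.6 in females and 9619 in males.

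The next comparison took the 6 chemosensory families. Odorant receptors, the ligand-gated channels of olfactory neurons, summed to 123.4 ± 4.46 CPM in females and 31.57 ± 7.41 CPM in males (SD, n = 3 per sex), 3.91-fold higher in females. The camera test placed the 22 tested receptors toward females relative to other unigenes (adjusted p = 4.13e-10), with a median log2 fold change of -1.74, or -1.69 with the 2 unigenes unlisted in a sex set at the listing limit. That call was lost with an estimated correlation (adjusted p = 0.105), while fry, which asks whether the members move one way on balance, gave an adjusted p of 0.0141. The exact two-sided permutation p of the summed level was 0.1, the smallest that 3 against 3 can give. In the same libraries muscle genes summed to 20127 CPM in males and 12248 CPM in females, and hemocyte and cuticle lists had medians of 0.72 and 0.74 toward males on the log2 scale. The hemocyte list summed to 5012 ± 1622 CPM in males and 3142 ± 1129 CPM in females (SD, n = 3 per sex; exact permutation p = 0.2). The cuticle list summed to 12296 ± 5114 CPM in males and 10703 ± 2612 CPM in females (SD, n = 3 per sex; exact permutation p = 0.8). Photoreceptor genes summed to 31789 CPM in males and 33682 CPM in females, and whether the libraries held tissue other than antennae was not determined.

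No odorant receptor passed the threshold over all tested unigenes (0 called, 6 with unadjusted p under 0.05 in edgeR, all higher in females). Adjusted over the list alone, 4 receptors were higher in females. The co-receptor Orco (Cluster-99082.27417), with which most odorant receptors form their channel, stood at 17.4 ± 3.55 CPM in females and 3.0 ± 1.72 CPM in males (SD, n = 3 per sex). Its log2 fold change female over male was 2.41 ± 0.45 (SE), with an edgeR adjusted p of 0.387 over all unigenes and 0.00921 over the list. Olfactory receptor 15 stood at 14.2 ± 3.15 CPM in females against 1.49 ± 0.358 CPM in males (SD, n = 3 per sex), with an edgeR adjusted p of 0.234 and 0.00317 respectively. The other 2, matching olfactory receptors 18 and 39 (Cluster-99082.39239 and Cluster-75883.4), were named after their values were seen and had edgeR adjusted p over the list of 0.00921 and 0.03. Cluster-75883.4 stood at 2.0 FPKM in females, near the listing limit of 0.3 FPKM, and was listed in 0 male libraries. Its log2 fold change of -7.62 rests on unlisted values entered as 0, and was -3.42 with them filled at 0.15 FPKM.

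Odorant-binding proteins, the soluble carriers of odorants in sensillum lymph, summed to 5552 ± 1450 CPM in females and 2979 ± 175 CPM in males (SD, n = 3 per sex; exact permutation p = 0.1, two-sided). Of 56 tested members 0 were called, over all unigenes or adjusted over the list alone, and 9 were higher in females and 1 in males at an unadjusted edgeR p under 0.05. The 2 most abundant matched pheromone-binding protein 2 (Cluster-99082.23894; 1135 ± 505 CPM in females, 407 ± 107 CPM in males) and a general odorant binding protein (Cluster-99082.19529; 877 ± 355 and 360 ± 87.9 CPM; SD, n = 3 per sex). In the Swiss-Prot database the best hit of Cluster-99082.19529 was general odorant-binding protein 2. General odorant-binding protein 1 (Cluster-99082.17039) stood at 532 ± 267 CPM in females and 177 ± 41.4 CPM in males (SD, n = 3 per sex), with an edgeR adjusted p of 0.587. The 2 unigenes matching pheromone-binding protein 3 (Cluster-99082.32171 and Cluster-99082.28069) had female to male ratios of 1.91 and 1.70 with edgeR adjusted p of 0.772 and 0.996.

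The median of the odorant-binding list went the other way, at 0.59 on the log2 scale toward males, as did the camera direction (adjusted p = 0.392; 0.842 with an estimated correlation). In this list 24 of the 56 tested members were listed in the 5 other libraries and unlisted in female replicate 2 alone. Their median was 0.90, while the 29 members listed in every file had a median of -0.33. Camera over unigenes listed in every file turned toward females (adjusted p = 0.0157; 0.458 with an estimated correlation). It also pointed to females without female replicate 2 (adjusted p = 0.929), and passed toward males without female replicate 3 (adjusted p = 0.0448). Without unigenes of foreign best hits, chosen after seeing the data, camera gave an adjusted p of 0.997. Among these 24 was the most abundant unigene with general odorant-binding protein 2 in its NR description (Cluster-99082.28982). It stood at 8.99 ± 7.79 CPM in females and 14.9 ± 6.32 CPM in males (SD, n = 3 per sex), far below Cluster-99082.19529. The pheromone-binding matches Cluster-99082.4414 and Cluster-99082.31303 were also among the 24. In that order the male to female ratios were 1.66, 1.32 and 1.64 (edgeR adjusted p = 0.996 for each), or 1.11, 0.878 and 1.09 without female replicate 2. The best protein hits of Cluster-99082.4414 and Cluster-99082.31303 were from the moth Ascotis selenaria cretacea. Like other unigenes unlisted in that library alone, they may come from another moth, as given below. The matches Cluster-71856.0 and Cluster-76163.1 had female to male ratios of 1.60 and 3.73 (edgeR adjusted p = 0.996 for both), the latter from 1.40 without female replicate 3 to 5.60 without female replicate 1 and 7.58 without male replicate 3.

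Chemosensory proteins, small soluble proteins of the sensillum lymph and other tissues, summed to 37406 ± 5109 CPM in males and 24455 ± 5258 CPM in females (SD, n = 3 per sex; exact permutation p = 0.1, two-sided). They were the most abundant of the 6 families. Camera placed the 28 tested members toward males (adjusted p = 9.83e-11, median log2 fold change 0.79), and the call was lost with an estimated correlation (adjusted p = 0.346). None was called over all unigenes (0, with 7 at an unadjusted edgeR p under 0.05, all higher in males), and 2 were higher in males adjusted over the list alone. The 2 most abundant (Cluster-99082.26121 and Cluster-99082.26548) stood at 16607 ± 5347 and 12462 ± 1823 CPM in males and 9300 ± 3541 and 9253 ± 1750 CPM in females (SD, n = 3 per sex), with edgeR adjusted p of 0.996 and 0.896. Of the list, 10 members were unlisted in female replicate 2 alone.

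Gustatory receptors summed to 26.98 ± 9.13 CPM in females and 35.04 ± 8.65 CPM in males, and ionotropic receptors to 538.3 ± 41.3 and 456.5 ± 102 CPM (SD, n = 3 per sex; exact permutation p = 0.4 and 0.3). Neither list passed camera (adjusted p = 0.132 and 0.147), and 0 of 12 and 0 of 25 tested members were called by edgeR, with 4 and 2 at an unadjusted p under 0.05. The 2 most abundant gustatory receptors, of the carbon dioxide receptor type by their hits (Cluster-117585.1 and Cluster-116323.1), had male to female ratios of 0.477 and 0.995. Past the threshold adjusted over the list alone were 2 unigenes that match gustatory receptor 67 (Cluster-9769.0 and Cluster-8896.0), listed in all 3 male and in 0 female libraries, and 1 unigene listed in females alone (Cluster-116323.0). These were named after their values were seen. Cluster-116323.0 stood at 0.867 FPKM in females, near the listing limit of 0.3 FPKM, and has the same hit descriptions as Cluster-116323.1. Whether it is a copy of that unigene was not determined. An NMDA-type glutamate receptor (Cluster-99082.6262) had a male to female ratio of 1.15. Of the ionotropic list, 1 ionotropic receptor (Cluster-40640.1, likewise named afterwards) was higher in females adjusted over the list alone (edgeR adjusted p = 0.0346). It stood at 1.59 FPKM in females, near the listing limit, and was listed in 0 male libraries. Its log2 fold change of -8.81 rests on unlisted values entered as 0, and was -3.18 with them filled at 0.15 FPKM.

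Sensory neuron membrane proteins, CD36-related proteins of pheromone-sensitive neurons and their support cells, summed to 214.7 ± 68.7 CPM in females and 134.6 ± 35.1 CPM in males (SD, n = 3 per sex; exact permutation p = 0.2). SNMP1 (Cluster-99082.29255) stood at 15.5 ± 4.53 CPM in females and 3.59 ± 1.21 CPM in males, a log2 fold change female over male of 1.96 ± 0.39 (SE), with an edgeR adjusted p of 0.422 over all unigenes and 0.00852 over the list. It was the 1 of 5 tested members past the threshold over the list alone, and camera gave the list an adjusted p of 0.179. A unigene with both an ionotropic receptor and an SNMP2 match (Cluster-99082.28914), counted in both lists, stood at 193 ± 65 CPM in females and 125 ± 34.5 CPM in males. It held 89.8% of the membrane protein sum in females and 92.8% in males. Without it that sum was 21.92 ± 7.2 CPM in females and 9.634 ± 1.81 CPM in males (SD, n = 3 per sex; exact permutation p = 0.1). The ionotropic receptor sum without it was 345.5 ± 24 CPM in females and 331.5 ± 68.5 CPM in males (SD, n = 3 per sex; exact permutation p = 0.9). The best SNMP2 match by its NR description (Cluster-87699.0) was unlisted in female replicate 2 alone, with a male to female ratio of 1.58, or 1.06 without that library. Its best protein hit was from the moth Ectropis obliqua, and it too may come from another moth. Over the 6 families together 0 of 143 tested unigenes were called by edgeR, 20 were higher in females and 10 in males at an unadjusted p under 0.05, and DESeq2 called 3. With reads summed per protein hit, edgeR called 2 chemosensory hits, gustatory receptor 67 toward males and olfactory receptor 15 toward females (adjusted p = 0.038 and 0.0489 over summed hits).

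**Figure D2:**
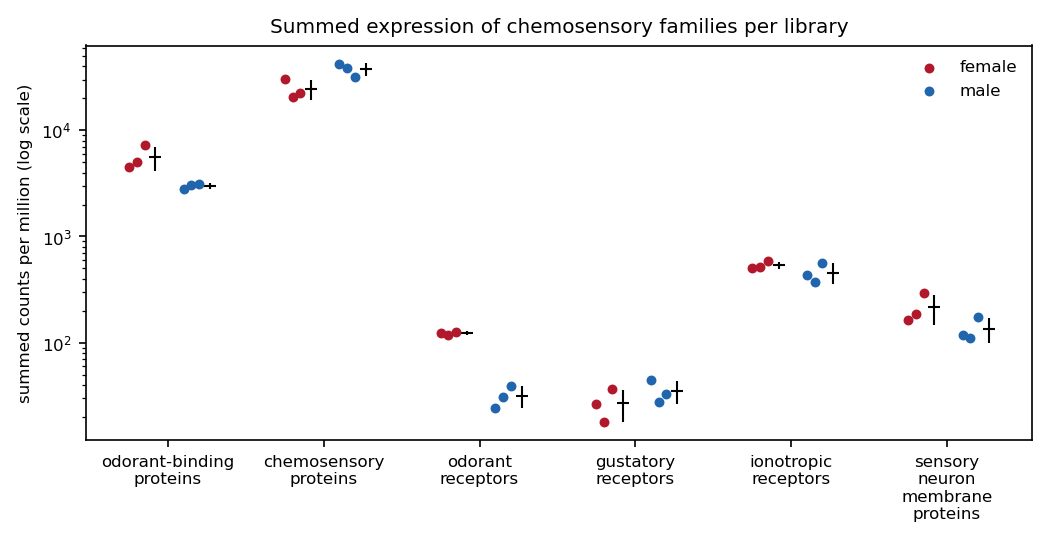
Summed CPM (log scale) of the 6 chemosensory families in each library, with points for the 3 libraries of a sex and a cross for the mean with its SD. Odorant receptors lie near 123.4 in females and 31.57 in males, and chemosensory proteins near 24455 and 37406.

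The remaining comparison took the other fixed lists. Muscle genes summed to 20127 ± 4595 CPM in males and 12248 ± 3301 CPM in females (SD, n = 3 per sex). Of its 102 tested members, 20 were higher in males and 1 in females at an unadjusted edgeR p under 0.05, with 0 called. Cuticle proteins had a median log2 fold change of 0.74 toward males over 151 members, cytosolic ribosomal proteins 0.65 over 314, mitochondrial respiratory chain genes 0.57 over 181, and hemocyte and immune genes 0.72 over 59. Camera placed these 5 lists toward males, with adjusted p of 1.18e-08, 4.03e-10, 2.59e-16, 2.25e-12 and 3.09e-06 in that order. With an estimated correlation the adjusted p were 0.346, 0.346, 0.424, 0.406 and 0.407. Of the ribosomal members 204, and of the mitochondrial 52, were unlisted in female replicate 2 alone. Over members listed in every file the medians were 0.50 (101) and 0.51 (108), and without that library camera gave adjusted p of 0.00139 and 8.99e-06. Glutathione S-transferases, aldehyde oxidases with alcohol dehydrogenases, heat shock proteins and tanning genes also lay toward males (camera adjusted p = 0.00151, 0.00678, 0.00104 and 0.0246), and UDP-glycosyltransferases, sensory cilium genes and transposon-derived transcripts toward females (0.00177, 0.0304 and 0.0299). The word pattern of the tanning list also took a viral RNA polymerase (Cluster-99082.26426), with 83.8% of the list's summed CPM in females and 85.4% in males, through the virus name. Without the 3 tested members matched by an organism name, a check chosen after seeing the data, the tanning list had a median of 0.25 and lost its call (camera adjusted p = 0.0702). The cilium list without 31 tested members matched by the adjective inactive or an organism name had a camera adjusted p of 0.0107. None of these 7 held with an estimated correlation (adjusted p between 0.346 and 0.406). Without female replicate 2, the aldehyde oxidase, tanning, cilium and transposon lists lost their camera calls (adjusted p = 0.371, 0.421, 0.371 and 0.388). Over unigenes listed in every file the aldehyde oxidase, cilium and transposon lists lost theirs (adjusted p = 0.133, 0.0667 and 0.299), and without unigenes of foreign best hits the transposon list did (adjusted p = 0.0512), both chosen after seeing the data. The aldehyde oxidase list also lost its call without male replicate 1, the tanning list without female replicate 1 or male replicate 1 or 3, the cilium list without female replicate 1 or male replicate 3, and the transposon list without any 1 male library (adjusted p between 0.0707 and 0.158). The UDP-glycosyltransferase list lost its call without male replicate 3 (adjusted p = 0.0863).

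Juvenile hormone and ecdysone genes held 1 of the 2 calls, the hormone binding protein, and summed to 16470 ± 1173 CPM in males and 8064 ± 729 CPM in females (SD, n = 3 per sex; exact permutation p = 0.1, two-sided). That sum rests on the hormone binding protein, without which it was 6851 ± 457 CPM in males and 7982 ± 715 CPM in females (SD, n = 3 per sex; exact permutation p = 0.2). The list as a whole did not pass camera (adjusted p = 0.635), with a median of -0.07 opposite to the direction of that test, and adjusted over the list alone 3 members were higher in males and 1 in females. Vitellogenin (Cluster-99082.27973), the egg yolk precursor, stood at 4891 ± 3110 CPM in females and 261 ± 382 CPM in males (SD, n = 3 per sex; edgeR adjusted p = 0.809). Its male libraries stood at 25.3, 56.6 and 701 CPM, and its log2 fold change of -4.15 became -6.62 without male replicate 3 (edgeR adjusted p = 0.165). The ovary and egg list summed to 6088 ± 2953 and 1158 ± 550 CPM (exact permutation p = 0.1; camera adjusted p = 0.789), and without vitellogenin to 1197 ± 325 and 896.6 ± 192 CPM (SD, n = 3 per sex; exact permutation p = 0.3). The best match to doublesex, a related transcription factor (Cluster-101806.0), had a male to female ratio of 0.845, and the best match to fruitless (Cluster-99082.34539) a ratio of 0.635, with edgeR adjusted p of 0.997 and 0.996.

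The lists of cytochrome P450s, carboxylesterases, fatty acyl desaturases and reductases, neuronal genes, amine and neuropeptide receptors, glial, photoreceptor, fat body, testis, sex determination, circadian clock and viral genes did not pass camera, with adjusted p of 0.705, 0.147, 0.529, 0.29, 0.454, 0.529, 0.175, 0.904, 0.179, 0.132, 0.958 and 0.839 in that order. The microbial list had 1 tested member and was not tested as a set. Each list's summed level had an exact permutation p of at least 0.1, and a Benjamini-Hochberg value of at least 0.22 over the 33 lists.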

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

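The test of foreign transcripts given here was chosen after the values it measures had been seen. Transcripts from organisms other than the wax moth appeared in the files, and they differed between female replicate 2 and the other 5 libraries. Female replicate 2 held 34822 unigenes listed in no other library, and none of them (0) entered the test between the sexes. In it, unigenes with a best nucleotide hit to rice or maize summed to 17598 CPM, to teleost fish 21111 CPM and to human 15041 CPM, against 272.1 to 356.3, 888.4 to 1266 and 439.9 to 663.2 CPM in the others. Among unigenes unlisted in female replicate 2, the other 5 libraries held 5716 with a best hit to grapevine, at 1328 to 3394 CPM, 393 to mouse, at 194 to 383.5 CPM, and 63 to geometrid moths, at 67 to 159.3 CPM. Over all unigenes with a mouse hit the sum was higher in female replicate 2, at 6214.9 CPM against 837.2 to 1250.2 CPM, and with a geometrid hit it was 3959 CPM against 4188.1 to 4742.9 CPM. Of the unigenes with a grapevine hit, 956 entered the test between the sexes, and a fit without unigenes of foreign best hits, chosen after seeing the data, also gave 2 calls.

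One candidate explanation is that reads from libraries of other studies were carried over within a shared sequencing pool, with female replicate 2 in another pool than the rest. If so, unrelated organisms would follow one profile over the 5 libraries, and over those unlisted in female replicate 2 the grapevine and mouse profiles differed by at most 0.24 on the log2 scale in any library, within the 0.5 set as the limit. Contact with such material before library preparation was not tested apart from this, and no biological explanation was tested. Because the geometrid transcripts include odorant-binding and chemosensory proteins, 36 tested chemosensory unigenes unlisted in female replicate 2 alone may in part come from another moth.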

How the results depend on the processing

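Fits called added were chosen after seeing the data; the cause of a change was not tested unless stated. The 2 unigene calls became 2582 with no filter (1715 of them listed in 1 library), 5 with a stricter filter, 7 over unigenes listed in every file (fewer unigenes, lower dispersion), 12 summed per protein hit, 196 by DESeq2, and in added fits 16 with unlisted values filled, 48 listed in every file with the block, 2 listed in every file without female replicate 2 and 209 by DESeq2 listed in every file. With no filter 496 were higher in males and 2086 in females. Leaving out a library gave 1 to 3, and 1 without female replicate 2, male replicate 1 or male replicate 2. Without male replicate 3, 3472 unigenes had an unadjusted edgeR p under 0.05, against 1459 to 1740 without any other library. The replicate block gave 0 calls (2033 unadjusted), and same-numbered libraries had deviation correlations of 0.07, 0.01 and -0.03 over all tested unigenes. Over unigenes listed in every file, however, adding the block raised the calls from 7 to 48 and the unadjusted count from 1888 to 2987. Whether the replicate numbers pair the libraries therefore stays open. Of the lists past camera, the block over all tested unigenes ended the calls of the cilium and transposon lists (adjusted p = 0.0597 and 0.053).

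Chemosensory calls, 0 in the reported fit, were 23 with no filter, 1 listed in every file, 3 by DESeq2, and in added fits 2 summed per protein hit, 1 with filled values, 6 listed in every file with the block and 13 by DESeq2 listed in every file; leaving out a library gave 0 each time. Adjusted over the list alone, the 11 calls became 28, 20, 4, 22, 20, 31 and 23 in the same order, and 5 to 10 with a library left out (5 without female replicate 3, 6 without male replicate 1). The 14 lists past camera became 0 with an estimated correlation, also over unigenes listed in every file (added), and 1 with fry; leaving out a library gave 10 to 16. The odorant-binding list turned toward females over unigenes listed in every file (added; adjusted p = 0.0157, and 0.458 with an estimated correlation) and without female replicate 2; with a library left out its adjusted p ranged from 0.0448 to 0.929.

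Male to female ratios of family sums kept their side of 1 under all alternatives except gustatory receptors, 1.30 as reported, 0.911 over unigenes listed in female replicate 2 and another library and 0.96 over those listed in it and a male library (both added, and both leave out by construction unigenes listed in males alone). With a library left out, the ratio ranged from 0.225 to 0.285 for odorant receptors and 0.489 to 0.63 for odorant-binding proteins. Of 422 alternative values for the 25 named unigenes, 6 changed sign, in 2 unigenes that were not called: Cluster-116323.1 (0.15 as reported; -0.44 to 0.67 with a library left out, -0.26 listed in every file without female replicate 2) and Cluster-101806.0 (-0.08 as reported; -0.41 to 0.28 with a library left out). Unigenes at or below 0.3 FPKM were unlisted, a limit of the files rather than of depth, and those just above it had a median of 3 reads per library, which limits low receptors.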

Other observations

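The tests of odorant receptor levels and of other groupings of the libraries were chosen after the results were seen; those of unigenes listed in 1 sex were written before, except that the one over unigenes holding at least 50% of their sum was added once the median over all had been seen. Photoreceptor transcripts were abundant in these antennal libraries, at 33682 ± 2202 CPM in females and 31789 ± 2126 CPM in males (SD, n = 3 per sex). Whether the libraries held eye tissue beside antennae was not determined, and CPM values are shares of all material in a library. A long-wavelength opsin (Cluster-99082.27789) stood at 9730 CPM in females and 10750 CPM in males, among the 10 most abundant unigenes, against 17.4 and 3.0 CPM for the olfactory co-receptor. The opsin was named after its values were seen.

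Odorant receptors were lower in the male libraries. Without female replicate 2 the male to female ratio of their sum was 0.251, which argues against the pool of that library as the whole cause. Over the 40 receptors listed in female replicate 2 and a male library, with 75.4% of the difference, the ratio was 0.284. This cannot decide on foreign reads, because foreign transcripts can be listed in both. Of 1439 unigenes with a mouse hit listed in female replicate 2, 761 were listed in it alone. Choosing receptors by listing in 1 female library may also favor those higher in females. Foreign reads therefore stay open for these 40 and for the other 72. A smaller share of olfactory tissue in the male libraries may lower receptors and carriers alike. Medians of the muscle, hemocyte and cuticle lists lay toward males in the same libraries, while that of photoreceptors did not. The summed cuticle level, however, was 1.15-fold higher in males with overlap of the sexes (exact permutation p = 0.8). The log2 ratio of receptors to pheromone-binding and general odorant-binding proteins lay between -5.42 and -5.28 in males and between -5.14 and -4.12 in females, a difference of -0.73 (exact permutation p = 0.1). That is over 2 SD of the males (SD 0.07) but not of the females (SD 0.51), so a smaller share cannot be told apart from a difference between the sexes in receptor expression, which was not tested separately.

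Another pattern was that 1196 unigenes were listed in all 3 female and no male library, and 717 in all 3 male and no female library. Such unigenes may be alternative assembled copies of genes present in both sexes: over those that share their best protein hit, levels summed over the hit had a median absolute log2 ratio of 0.68, but the unigene made up a median of 40.7% of its sum, so the sum could stay within 2-fold without any other copy making up for it. Over the 234 that held at least 50% of their sum the median was 1.11 (95% bootstrap interval 0.91 to 1.27), which includes the value of 1 that separates the cases, so the explanation stays open. Transcripts limited to females, as from the W chromosome that female moths carry, could also raise the female count, but of the 20 groups of 3 libraries one that mixed the sexes gave 1445, so this stays open too. That group was female replicates 1 and 3 with male replicate 1. These libraries listed the most unigenes with a grapevine hit (4037, 4408 and 4851). How many of the 1445 had foreign hits was not counted, so the group is a limited comparison.

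The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 2 unigenes and 1 of the 10 splits, itself, gave as many, the highest of the others being 0. Among unigenes listed in every file the real split gave 7 and the highest other 0, and for gene lists past camera the real split gave 14 and the highest other 11.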
